A study of Mus musculus with 15 samples.

How the data were processed

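Livers of 15 wild-type mice were profiled by RNA sequencing, with 5 libraries from each of 3 groups, named Vehicle, GDF15 and PairFed. Per the labels' protocols, total RNA was extracted with TRIzol and RNeasy columns and made into libraries with a directional kit, which keeps the strand of the RNA. Salmon, which estimates counts per transcript, and DESeq2 are named in the submitters' processing notes without versions or roles, together with the mouse build mm10. The table deposited by the authors holds whole-number estimated counts per gene symbol for 15302 genes, not scaled to depth; that these are rounded Salmon estimates is a reading of the submitters' processing notes. Every gene in the table had a sum of at least 5 over the 15 libraries, and no mitochondrially encoded gene was in it. The transcript set and the strand setting of the counting are not given in the sources used here. Counts of overlapping or antisense genes and of near-identical copies can therefore hold each other's reads.

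Columns were assigned to groups by their names. Within a group, the column of each animal could not be tied to an animal's label, so libraries are numbered by their order in the table, as names only. No paired analysis was possible because nothing in the sources ties a PairFed animal to a GDF15 animal. Gene positions are from the RefSeq table of assembly GRCm38.p6, whose primary sequences are those of mm10; 15289 of the 15302 symbols matched it.

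Genes were filtered with filterByExpr in edgeR 4.0.16 (R 4.3.3) at its settings of a count of 10 and a total count of 15, which left 12274 genes holding 99.9% of the counts. Libraries were scaled by the trimmed mean of M-values (TMM). A single model of the 15 libraries was fitted with edgeR's quasi-likelihood test with robust estimation, and the contrasts GDF15 vs Vehicle, PairFed vs Vehicle and GDF15 vs PairFed were tested in it. The p-values were adjusted by Benjamini-Hochberg over the tested genes of each contrast, and a gene was said to have changed at an adjusted p below 0.05. Adjusted p-values of genes in the text are from this test unless another is named. Standard errors (SE) of log2 fold changes were derived from the F statistic, and means with standard deviations (SD) are of CPM, the count as a share of the library total scaled by TMM, computed here.

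These choices, the gene lists and the rule for naming genes were fixed before the data were examined. 33 gene lists were written from general knowledge of liver, immune cells, glucocorticoid response and feeding, and the 30 with at least 5 tested members were tested with camera in limma 3.58.1 on voom values, two-sided, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. Each was also tested with an estimated correlation and with fry, and its members were counted as changed over all genes tested and adjusted over the list alone. List scores are the mean log2 CPM of the tested members in a library, with a prior count of 2. The genes named were, in each contrast, up to 6 with the largest rise and 6 with the largest fall among those past the threshold with a mean log2 CPM of at least 1 and groups that did not overlap, up to 2 members of each list, and 24 genes of interest to the study's question. Not all of them are printed, and genes named outside this rule are given as such.

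Total counts ran from 8551557 to 12994187 per library. The common biological coefficient of variation was 13.3%. On simulated counts for 12274 genes with 5 libraries per group and 200 genes changed, the test recovered 55.6% of changes of 0.5 log2, 83.6% of changes of 1 and 98.5% of changes of 2 in GDF15 vs Vehicle, with 3 false calls among 159. In the simulated GDF15 vs PairFed contrast it recovered 52.4%, 83.6% and 98.5% of these sizes, with 8 false calls among 162. In the simulated PairFed vs Vehicle contrast, in which no gene differed, it made 1 call. With 30 simulated lists, camera called the changed list and none of the 29 unchanged lists with either correlation. The simulated genes were drawn independently of each other, so this could not show false calls that come from correlation between members. In the real lists the estimated correlation reached 0.75 (endothelial markers, PairFed vs Vehicle).

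Alternatives tried were DESeq2 size factors or upper-quartile factors in place of TMM, no filter or a filter of 10 CPM in 5 libraries, the Wald test of DESeq2 1.42.0, limma-voom, a fit of only the groups compared, 1 surrogate variable from sva 3.50.0, a minimum change of 1 log2 unit, and leaving out each library in turn. Added after the data were seen were a term for the sets of libraries parted by the largest gap in total count, a fit of only the libraries below that gap, a score of clock genes or of immediate-early genes as a covariate, and counts thinned to the smallest total. The number of genes called in regrouped libraries was counted over 100 splits, drawn from the 126 possible ones in each contrast. Exact permutation tests of scores were two-sided over 252 regroupings.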

Results

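RNA from the liver of 15 wild-type mice was sequenced. From 8 weeks of age the animals had been on a diet that brings on metabolic dysfunction-associated steatohepatitis (MASH), a fatty and inflamed state of the liver, and were housed at about 29°C. The 5 GDF15 animals received the recombinant hormone GDF15, which lowers food intake through a receptor in the hindbrain, under the skin at 1 nmol/kg once daily. The 5 Vehicle animals served as controls, and the 5 PairFed animals were given the amount of food that the GDF15 group had eaten the day before. Total counts ran from 9228127 to 12994187 in Vehicle, from 8551557 to 10914914 in GDF15 and from 10133289 to 12933324 in PairFed. The largest gap in total count lay between 10914914 and 12137462. It parted 10 shallower from 5 deeper libraries, and the deeper ones were Vehicle 4 and PairFed 2 to 5. No GDF15 library was deeper, so depth and group were partly tied. The first principal component held 24.9% of the variance and the second 12.3%. In each contrast 12274 genes were tested.

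Because GDF15 was given as a protein, the liver's own Gdf15 transcript does not check the group labels. Its level was 137 ± 70.2 CPM in GDF15, 83.5 ± 58.3 CPM in Vehicle and 81.7 ± 45.5 CPM in PairFed (mean ± SD, n = 5 each). The difference from Vehicle was not past the threshold of edgeR's quasi-likelihood test (log2 fold change 0.71 ± 0.50 SE, adjusted p = 0.524), and its sign turned with an immediate-early covariate.

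GDF15 was compared with Vehicle for the whole effect of the treatment on the liver, reduced food intake included. 356 genes changed, 248 of them higher and 108 lower. Genes induced by glucocorticoids, the adrenal steroid hormones, rose together: 13 of the 30 tested members rose and none fell (22 rose when adjusted over the list alone), with a list median of 0.99 log2 or 1.98-fold. Fkbp5, a co-chaperone induced by the glucocorticoid receptor, rose from 26.2 ± 4.25 to 85.1 ± 19.1 CPM (mean ± SD, n = 5 each), a log2 fold change of 1.69 ± 0.16 (SE, adjusted p = 6.95e-05). Zbtb16, a transcription factor, rose by 1.83 ± 0.25 (adjusted p = 0.00228), and Lpin1, an enzyme of triglyceride synthesis, by 1.90 ± 0.27 (adjusted p = 0.00234). Tsc22d3, which carries part of the anti-inflammatory action of glucocorticoids, rose by 0.74 ± 0.15 (adjusted p = 0.0138). Per1, a clock gene that is also a receptor target, rose by 1.32 ± 0.24 (adjusted p = 0.0121). Fkbp5 lies on chromosome 17 at 28398753 to 28486149, Zbtb16 on chromosome 9 at 48651797 to 48836225 and Tsc22d3 on chromosome X at 140539528 to 140600522 of the mm10 assembly. Nr3c1, the glucocorticoid receptor itself, differed by 0.06 ± 0.08 (adjusted p = 0.778), and the sign turned without GDF15 5 and with a clock phase or immediate-early covariate. Hsd11b1, which regenerates active glucocorticoid in the liver, differed by 0.32 ± 0.13 (adjusted p = 0.212). In the list of genes for GDF15, its receptor, steroid handling and adrenergic receptors, 1 of the 12 tested members rose (4 adjusted over the list alone), with a median of 0.35 (adjusted p = 0.104 with an estimated correlation). That member was Akr1d1, a reductase of steroid hormones and bile acid precursors, at 0.45 ± 0.11 (adjusted p = 0.0427). Gfral, the gene of the GDF15 receptor, was not in the count table and so was not among the 12.

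Immediate-early genes, which respond within minutes to stimuli and to handling, moved with the glucocorticoid genes. Of their 20 tested members, 0 were past the threshold of edgeR's test over all genes, 13 rose when adjusted over the list alone, and the list was higher with a median of 0.96 (adjusted p = 6.96e-07, and adjusted p = 0.143 with an estimated correlation). Without the member shared with the glucocorticoid list, their score was higher by 0.84 in GDF15 than in Vehicle (exact permutation p = 0.0397). With that score as a covariate, edgeR's test called 9 genes in place of 356, among them Fkbp5, Sds, Cps1 and Gin1. In that fit 2 of the 13 glucocorticoid-induced genes stayed past the threshold: Fkbp5 stood at 1.37 ± 0.17 (adjusted p = 0.00551) and Sds at 1.18 ± 0.18 (adjusted p = 0.0153). The median of the 13 went from 1.57 to 0.83.

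**Figure D1:**
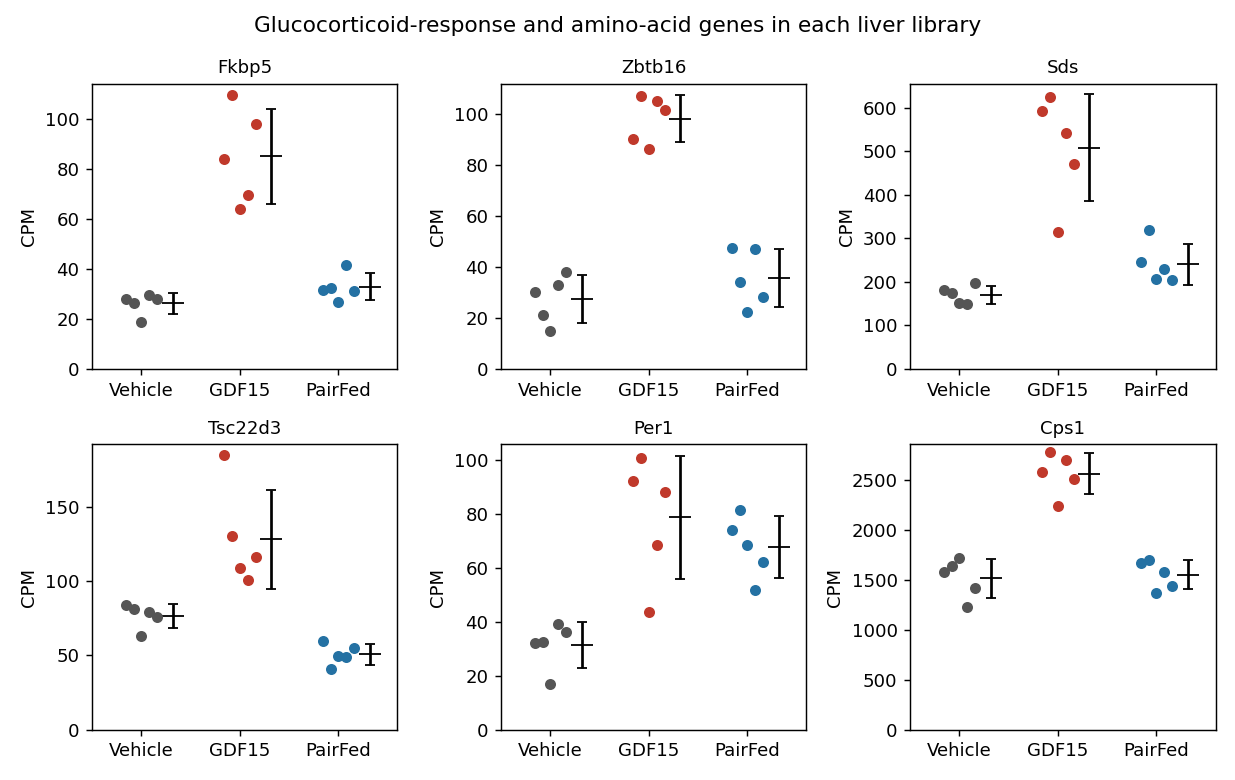
Expression of Fkbp5, Zbtb16, Sds, Tsc22d3, Per1 and Cps1 in CPM (y axis) in each of the 15 liver libraries, by group (x axis). Points are libraries and the bar beside them is the mean with the SD (n = 5); Fkbp5 was at 85.1 CPM in GDF15, 26.2 in Vehicle and 32.8 in PairFed.

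Genes of glucose production and amino acid breakdown rose as well. Of the 30 tested members, 18 rose and none fell (26 rose when adjusted over the list alone), with a median of 0.65. Sds, which breaks down serine, rose by 1.57 ± 0.17 (adjusted p = 0.000274). The urea cycle genes Cps1 and Ass1 rose by 0.76 ± 0.09 (adjusted p = 0.000274) and 0.75 ± 0.11 (adjusted p = 0.00154). This list shares 6 members with the glucocorticoid list, and without them 16 of the other 24 rose. Pck1, which controls glucose production and is among the shared members, was at 1.31 ± 0.33 (adjusted p = 0.0539). Together with the glucocorticoid list and the chemokine list, this list kept its call with an estimated correlation (adjusted p = 0.0462 for each of the 3). With the depth term as well, none of the 3 did (adjusted p = 0.105 for each). Of 30 hepatocyte genes, 7 rose (13 adjusted over the list alone), with a median of 0.21 (adjusted p = 0.104 with an estimated correlation). Without the members shared with the amino acid and glucocorticoid lists, 3 of 26 rose, with a median of 0.16.

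Several lists of liver metabolism were higher with few members past the threshold. In lipogenesis, 4 of 27 members rose (7 rose and 1 fell when adjusted over the list alone), with a median of 0.14 (adjusted p = 0.225 with an estimated correlation). Among them were Fads1 and Fads2, the desaturases of polyunsaturated fatty acids, at 0.55 ± 0.09 and 0.49 ± 0.10. Each of the 25 genes of the cholesterol list had a positive fold change, with a median of 0.27 (adjusted p = 0.325 with an estimated correlation). In fatty acid oxidation 1 of 34 members rose (3 adjusted over the list alone), the lipid droplet protein gene Plin5, at 0.62 ± 0.13 (list adjusted p = 0.325 with an estimated correlation). In bile acid and sterol handling 2 of 23 rose (4 adjusted over the list alone), Cyp27a1 at 0.59 ± 0.09 and Cyp2c70 at 0.68 ± 0.17, both enzymes of bile acid synthesis (list adjusted p = 0.225 with an estimated correlation). In drug metabolism 2 of 28 rose (9 rose and 1 fell when adjusted over the list alone), the pregnane X receptor gene Nr1i2 at 0.54 ± 0.11 and Por, the reductase that serves the cytochromes P450, at 1.18 ± 0.26 (list adjusted p = 0.104 with an estimated correlation). Of 22 clock genes, 3 rose (5 adjusted over the list alone), with a median of 0.42 (adjusted p = 0.104 with an estimated correlation). They were Per1, Cry2 at 0.45 ± 0.10 and Ciart at 2.47 ± 0.54, all repressors within the clock. Ciart and Upp2, a uridine phosphorylase, had the largest rises among the genes that met the naming rule, at 5.52-fold and 5.15-fold. Pim3, a kinase, rose 3.57-fold, and Hamp2, a copy of the hepcidin gene with which it can share reads, rose 3.50-fold. Mean CPM in Vehicle, GDF15 and PairFed was 2.34, 13.7 and 10.8 for Ciart and 56.7, 294 and 166 for Upp2. For Pim3 it was 46.2, 165 and 119, and for Hamp2 43.5, 153 and 65.6. The mean of each was thus also higher in PairFed than in Vehicle. Herpud1, which acts in the degradation of misfolded proteins, rose by 0.66 ± 0.12 (adjusted p = 0.00645), while the list of endoplasmic reticulum stress genes was not past its threshold (median -0.17, adjusted p = 0.0661). In the acute-phase list 2 of 25 members rose and 2 fell (adjusted p = 0.689 for the list). Serpina3m rose by 0.55 ± 0.11 and Orm2 was at -0.60 ± 0.12, and both belong to families whose copies can share reads.

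Genes of antigen presentation and chemokines fell. Of the 9 tested genes of the MHC class II pathway, which shows antigens to T cells, 5 fell and none rose (9 fell when adjusted over the list alone), with a median of -0.84 (adjusted p = 6.59e-11, and adjusted p = 0.104 with an estimated correlation). H2-DMa and H2-DMb1, which load peptides onto class II molecules, were 1.84-fold and 1.79-fold lower (adjusted p = 0.00259 and 0.00228), and H2-DMb1 can share reads with its copy. Of 17 tested chemokine and cytokine genes, 3 fell and none rose (6 fell when adjusted over the list alone), with a median of -0.52 (adjusted p = 3.97e-06, and adjusted p = 0.0462 with an estimated correlation). The T cell attractants Cxcl10 and Ccl5 were 2.21-fold and 2.76-fold lower (adjusted p = 0.00222 and 0.0192). Ccl2, which draws in monocytes, was at -0.97 ± 0.35 (adjusted p = 0.150) and Il1b at -0.83 ± 0.35 (adjusted p = 0.234). Tnf had 50 counts over the 15 libraries and was not tested. Ubd, a ubiquitin-like gene induced by inflammatory cytokines, was 2.74-fold lower (adjusted p = 0.00645). Of 31 interferon-induced genes, 2 fell (8 adjusted over the list alone), Gbp2 and Ifit3b, the second of which can share reads with its copy. Gbp2 had an adjusted p = 0.0241 (0.0391 with the depth term) and Ifit3b an adjusted p = 0.0498 (0.0666 with the depth term). The list median was -0.31 (adjusted p = 0.215 with an estimated correlation). Among 19 targets of NF-kB, 1 fell, Tnfaip2 (4 adjusted over the list alone), with a list median of -0.38 (adjusted p = 0.104 with an estimated correlation). With the immediate-early score as a covariate, H2-DMa, H2-DMb1, Cxcl10 and Ccl5 were not past the threshold (adjusted p = 0.195, 0.258, 0.146 and 0.706), and the MHC class II list had a median of -0.62 with 9 of 9 members below 0. Outside these lists, the heat shock gene Hspa1b, which can share reads with a near-identical copy, was 2.84-fold lower, and Ppp1r16b, Gdf6 and Ddit4l were 2.58-fold, 2.29-fold and 2.21-fold lower.

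Several lists of immune cell markers had negative medians, and those past the threshold lost their call with an estimated correlation. All 18 tested markers of recruited monocytes had negative fold changes, with a median of -0.40 (adjusted p = 0.104 with an estimated correlation), and 1 fell, Ly6c2. Of 8 tested T and NK cell genes, 2 fell, among them Cd8a, and Zap70 rose; the median was -1.24 (adjusted p = 0.171 with an estimated correlation). Cd8a was at 0.411 CPM in GDF15 and 1.71 CPM in Vehicle, near the floor of detection. The 7 dendritic cell markers had a median of -0.35 (adjusted p = 0.104 with an estimated correlation). The 20 genes of lipid-associated macrophages, which gather in MASH, had a median of -0.33 (adjusted p = 0.225 with an estimated correlation), with Trem2 at -0.47 ± 0.18 (adjusted p = 0.190) and Spp1 at -0.68 ± 0.28 (adjusted p = 0.236). The 34 genes of stellate cells and fibrosis had a median of -0.28 (adjusted p = 0.497 with an estimated correlation) and the opposite direction with a surrogate variable (adjusted p = 0.0610), with Col1a1 at -0.62 ± 0.37 (adjusted p = 0.440) and Timp1 at -0.76 ± 0.27 (adjusted p = 0.150). In the bile duct and progenitor list 1 of 15 members fell, Krt18, at -0.31 ± 0.08 (adjusted p = 0.0498, and adjusted p = 0.0534 with the depth term). That list had an adjusted p = 0.325 with an estimated correlation. Cell cycle genes had a median of -0.33 (adjusted p = 0.510 with an estimated correlation) and antioxidant genes of -0.05 (adjusted p = 0.510 with an estimated correlation). The lists of resident Kupffer cells, the macrophages of the liver, and of endothelial cells were not past the threshold (adjusted p = 0.706 for both), nor were those of B and plasma cells and of blood (adjusted p = 0.272 for both) and of growth hormone response (adjusted p = 0.477). In the last list 1 of 27 members fell, Selenbp2, which can share reads with its copy. The Kupffer list had a median of -0.03 and a mean of 0.14, so their signs differed, and Clec4f, a Kupffer cell marker, was at 0.22 ± 0.18 (adjusted p = 0.577). GDF15 1 had the lowest MHC class II score of the 15 libraries, at -1.24, and also the lowest Kupffer score (-0.62) and endothelial score (-0.95) relative to the Vehicle mean. Without it, 3 of the 5 MHC class II genes stayed past the threshold and the list median was -0.78. Of the lists with too few tested members, that of neutrophils had 3, that of neighbouring tissues 2 and that of mitochondrial genes 0.

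**Figure D2:**
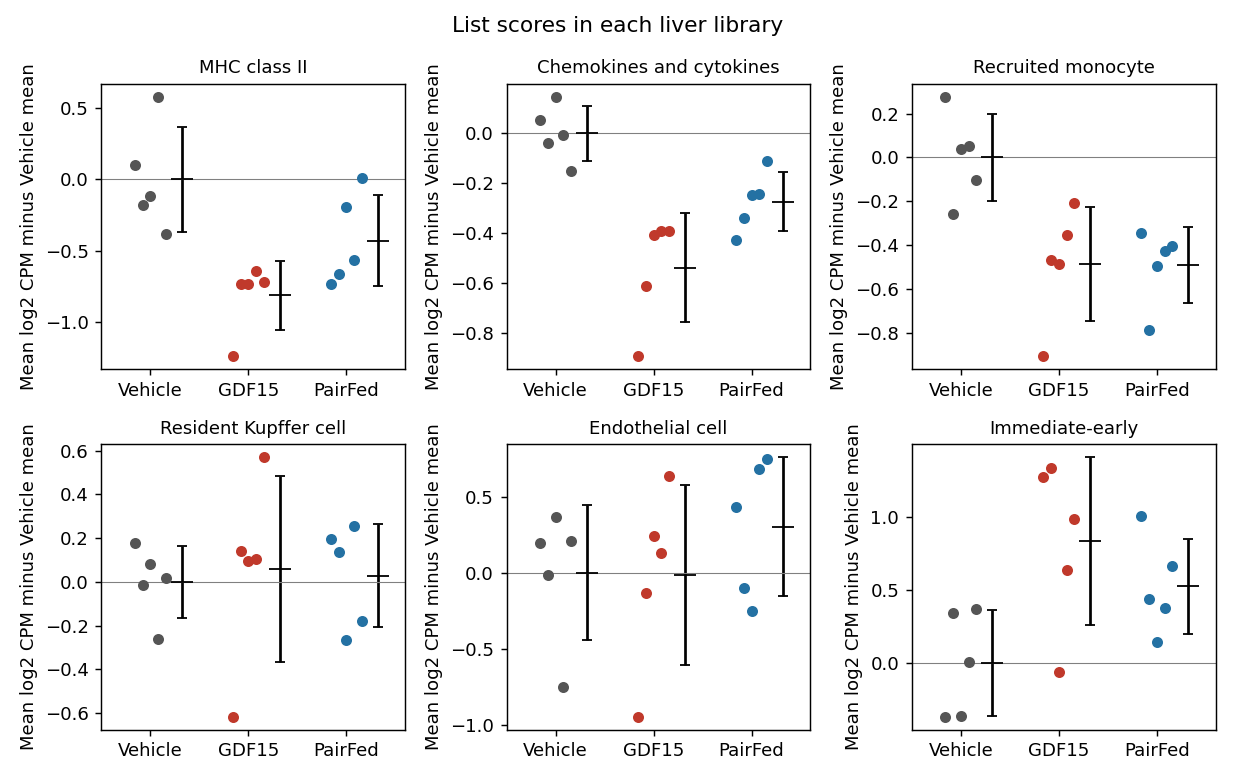
Scores of 6 gene lists in each of the 15 liver libraries, by group (x axis), as mean log2 CPM of the members minus the Vehicle mean (y axis). Points are libraries and the bar beside them is the mean with the SD (n = 5); the 5 GDF15 libraries lie between -1.24 and -0.64 for MHC class II, while the Kupffer cell scores of the 3 groups overlap.

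At the same threshold DESeq2 called 642 genes and limma-voom 310 in this contrast, and 60 of the 356 genes changed at least 2-fold. In 266 of the 356 the groups did not overlap; among all genes this held for 490, or 3.99% against 0.794% by chance. The count fell to 152 without Vehicle 1, 178 without Vehicle 3, 172 without GDF15 1 and 134 without GDF15 2, and was 195 in a fit of the 2 groups alone and 157 with a surrogate variable. Among the shallower libraries, 5 GDF15 and 4 Vehicle, 156 genes changed, and with a term for the deeper libraries 364 did, 290 of them shared with the 356. The share of higher genes was 69.7% and became 58.7% with upper-quartile scaling. Of the 43 named genes that changed, 21 stayed past the threshold without each library in turn, among them Fkbp5, Zbtb16, Lpin1, Tsc22d3, Per1, Sds, Cps1, Ass1, H2-DMa, H2-DMb1, Cxcl10 and Ubd.

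PairFed was compared with Vehicle for the effect of eating as little as the GDF15 group without receiving GDF15. 35 genes changed, 18 higher and 17 lower, and 2 of them at least 2-fold. Sox9, a transcription factor of bile duct and progenitor cells, was 2.47-fold lower (log2 fold change -1.31 ± 0.24, adjusted p = 0.0336), with 6.05 ± 1.69 CPM in PairFed (mean ± SD, n = 5). Lpl, the lipase that frees fatty acids from lipoproteins, was 1.58-fold lower (adjusted p = 0.0449), and Slc22a7, an organic anion transporter, 1.66-fold lower (adjusted p = 0.0327). Dynll1, a dynein light chain, was 1.62-fold lower, and H2-M2 and Mug-ps1, which can share reads with their relatives, were 2.82-fold and 1.57-fold lower. Among the genes that rose were Txnrd3, a thioredoxin reductase, at 0.69 ± 0.11 (adjusted p = 0.0240), Pdzrn3 at 0.61 ± 0.10 (adjusted p = 0.0250) and Rnf43, a brake on Wnt signalling, at 0.52 ± 0.09 (adjusted p = 0.0327). Tlr5, the flagellin receptor, Slc46a3, a lysosomal transporter, and Slc20a1, a phosphate transporter, rose by 0.52, 0.51 and 0.51. The desaturase genes Fads1 and Fads2 rose by 0.46 ± 0.09 and 0.51 ± 0.10, and they were the only called members of the lipogenesis list. That list was not past its threshold (adjusted p = 0.719); its median was -0.05 while the test pointed up. With the depth term it was past the threshold at the preset correlation, with a median of 0.16 (adjusted p = 0.000935, and adjusted p = 0.313 with an estimated correlation).

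In PairFed, 20 lists were past the threshold with the preset correlation and none with an estimated correlation, whose lowest adjusted p was 0.272. The glucocorticoid-induced list had a median of 0.42, with 0 of 30 members past the threshold of edgeR's test (3 rose and 1 fell when adjusted over the list alone; adjusted p = 0.345 with an estimated correlation). Of its members, 27 had positive and 3 negative fold changes, and no single one was past the threshold: Fkbp5 was at 0.32 ± 0.16 (adjusted p = 0.319), Per1 at 1.10 ± 0.24 (adjusted p = 0.0735), Pnpla2, a triglyceride lipase, at 0.51 ± 0.12 (adjusted p = 0.0715) and Tsc22d3 at -0.60 ± 0.15 (adjusted p = 0.0792). In glucose production and amino acid breakdown the median was 0.35, with 0 of 30 members past the threshold (11 rose when adjusted over the list alone; adjusted p = 0.272 with an estimated correlation). Gpt2, an alanine transaminase, was at 0.34 ± 0.07 (adjusted p = 0.0578), and Pck1 at 0.87 ± 0.33 (adjusted p = 0.204). The cholesterol list had a median of 0.29 (23 of 25 members positive), drug metabolism of 0.23 (25 of 28) and fatty acid oxidation of 0.17 (30 of 34). With GDF15 against Vehicle these medians were 0.27, 0.26 and 0.10. None of these lists had a called member in PairFed (adjusted p = 0.490, 0.272 and 0.286 with an estimated correlation). Recruited monocyte markers had a median of -0.42 (9 fell when adjusted over the list alone; adjusted p = 0.272 with an estimated correlation). MHC class II genes had a median of -0.48 (7 fell when adjusted over the list alone; adjusted p = 0.272 with an estimated correlation), and their regulator Ciita was at -0.79 ± 0.19 (adjusted p = 0.0735). Chemokines had a median of -0.29 (adjusted p = 0.272 with an estimated correlation), with Cxcl10 at -0.61 ± 0.17 (adjusted p = 0.0972) and Ccl2 at -0.37 ± 0.33 (adjusted p = 0.595), whose sign turned with the depth term and the clock phase covariate. Genes of endoplasmic reticulum stress had a median of -0.36, and of -0.18 with the depth term (11 fell when adjusted over the list alone without it, with adjusted p = 0.272 with an estimated correlation). Creld2, a chaperone of that compartment, was at -0.87 ± 0.17 (adjusted p = 0.0503). Clock genes had a median of 0.37, and of 0.19 with the depth term (7 rose and 4 fell when adjusted over the list alone without it, with adjusted p = 0.272 with an estimated correlation). Cry2 was at 0.45 ± 0.09 (adjusted p = 0.0514). Lipid-associated macrophage genes had a median of -0.31, with Lpl the only member that fell (adjusted p = 0.539 with an estimated correlation), Trem2 at -0.58 ± 0.18 (adjusted p = 0.133) and Spp1 at -0.59 ± 0.28 (adjusted p = 0.303). The fibrosis list was not past its threshold (median -0.20, adjusted p = 0.0536; median -0.01, adjusted p = 0.803 with the depth term), with Col1a1 at -0.55 ± 0.36 (adjusted p = 0.471) and Timp1 at -0.52 ± 0.26 (adjusted p = 0.309). Endothelial markers had a median of 0.32, and of 0.77 with the depth term, with 0 of 22 members past the threshold (adjusted p = 0.575 with an estimated correlation, without the term). Bile duct and progenitor markers had a median of -0.59, with Sox9 the only called member (adjusted p = 0.397 with an estimated correlation).

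At the same threshold DESeq2 called 339 genes and limma-voom 38, and 2076 genes had an unadjusted p below 0.05 in edgeR's test. The share of higher genes was 51.4% and became 32.5% with upper-quartile scaling. The groups did not overlap in 32 of the 35 genes, and in 481 of all genes, or 3.92% against 0.794% by chance. 4 of the 5 PairFed libraries but 1 of the 5 Vehicle libraries were deeper, and with a term for the deeper libraries edgeR's test called 0 genes (1361 at an unadjusted p below 0.05; limma-voom 0 and DESeq2 62). It also called 0 without Vehicle 1 (1766; 0 and 183), without Vehicle 3 (1517; 0 and 144), without PairFed 2 (1710; 0 and 176) and without PairFed 4 (1780; 0 and 132), the values in parentheses being the genes at an unadjusted p below 0.05, then those called by limma-voom and DESeq2. The count was 11 without Vehicle 2, 94 without Vehicle 5, 22 without GDF15 2, 54 without GDF15 3, 18 without GDF15 4, 135 without PairFed 1 and 11 without PairFed 5. None of the 14 named genes that changed stayed past the threshold without each library in turn. The clock phase score was higher by 1.83 in PairFed than in Vehicle (exact permutation p = 0.0476), and with it as a covariate 6 genes were called. The immediate-early score was higher by 0.55 (exact permutation p = 0.0476), and with it as a covariate edgeR's test called 0 genes (1347 at an unadjusted p below 0.05; limma-voom 0 and DESeq2 62).

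GDF15 was compared with PairFed for the part of the response that matched food intake did not give, which is also the direct test of a difference between them. 96 genes changed, 69 higher and 27 lower. Of the 30 glucocorticoid-induced genes, 6 were higher with GDF15 and none lower (12 higher when adjusted over the list alone), with a list median of 0.59 (adjusted p = 7.37e-12, and adjusted p = 0.420 with an estimated correlation). Fkbp5 was at 85.1 ± 19.1 CPM in GDF15 and 32.8 ± 5.41 in PairFed (mean ± SD, n = 5 each), a log2 fold change of 1.37 ± 0.16 (SE, adjusted p = 0.000652). Tsc22d3 was higher by 1.33 ± 0.15 (adjusted p = 0.000491), Zbtb16 by 1.46 ± 0.24 (adjusted p = 0.0178), Lpin1 by 1.48 ± 0.26 (adjusted p = 0.0253) and Sds by 1.08 ± 0.17 (adjusted p = 0.00977). Per1, which was higher than in Vehicle with GDF15, differed from PairFed by 0.22 ± 0.23 (adjusted p = 0.749), with the opposite sign under an immediate-early covariate.

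In glucose production and amino acid breakdown, 4 of 30 members were higher (14 adjusted over the list alone), with a median of 0.31 (adjusted p = 0.420 with an estimated correlation). Cps1 was higher by 0.72 ± 0.09 (adjusted p = 0.000652), and it and Ass1, at 0.50 ± 0.11 (adjusted p = 0.0443), were among the 3 of 30 hepatocyte genes that were higher (11 adjusted over the list alone; list median 0.12, adjusted p = 0.494 with an estimated correlation). Slc22a7, the organic anion transporter, was 2.49-fold higher (adjusted p = 4.33e-05): it stood above Vehicle with GDF15 and below Vehicle in PairFed, both past the threshold. Slc2a4, the insulin-responsive glucose transporter gene, was 2.81-fold higher at a low level, 5.34 ± 2.39 against 1.90 ± 0.549 CPM. The bile acid genes Cyp27a1 and Cyp2c70 were higher by 0.54 ± 0.09 and 0.85 ± 0.17, while their list was not past its threshold (adjusted p = 0.219). Plin5 was higher by 0.77 ± 0.13 in a fatty acid oxidation list that was not past its threshold either (median -0.05, adjusted p = 0.247). The lipogenesis list had a median of 0.27 (adjusted p = 0.645 with an estimated correlation), and its direction turned with the depth term (adjusted p = 0.719). Herpud1 was higher by 0.62 ± 0.12 and the only called member of the endoplasmic reticulum stress list (median 0.22, adjusted p = 0.645 with an estimated correlation). Il1r1, the receptor of interleukin 1, was 2.15-fold higher and the only called member of the acute-phase list (median 0.03, adjusted p = 0.730 with an estimated correlation). Among the genes that were lower than in PairFed, Bhlhe41, a repressor of the clock, was 3.77-fold lower and Cntnap1, a cell adhesion gene, 2.46-fold. The linker histone gene H1f2 was 1.60-fold lower, Nceh1, a cholesterol ester hydrolase, 1.45-fold and Gpc1, a heparan sulphate proteoglycan, 1.44-fold. Ppp1r16b was at -1.38 ± 0.29 log2. Mean CPM in Vehicle, GDF15 and PairFed was 2.44, 1.73 and 6.54 for Bhlhe41 and 41.6, 39.6 and 57.3 for Nceh1. It was 52.6, 50.8 and 73.1 for Gpc1, so these differences lay mainly in a higher PairFed level. For Ppp1r16b it was 2.43, 0.934 and 2.47, with GDF15 the group apart. For Cntnap1 and H1f2 the Vehicle mean lay between those of the other groups. With a term for the deeper libraries Bhlhe41 was at -0.62 ± 0.33 (adjusted p = 0.624), against -1.91 ± 0.39 without it. It was also not past the threshold with limma-voom, with the immediate-early covariate or without any 1 of Vehicle 5, PairFed 2 to 5 and the 5 GDF15 libraries (adjusted p from 0.00316 to 0.624 over its alternatives). With the depth term H1f2 was at -0.42 ± 0.13 (adjusted p = 0.328), against -0.68 ± 0.10 without it. Cntnap1, Nceh1, Gpc1 and Ppp1r16b also lost their calls in that fit.

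No member of the inflammatory lists differed between GDF15 and PairFed in edgeR's test, apart from Il1r1. MHC class II genes had a median of -0.27 (0 of 9 past the threshold, 2 lower when adjusted over the list alone; adjusted p = 0.00450, and adjusted p = 0.730 with an estimated correlation), with H2-DMa at -0.45 ± 0.15 (adjusted p = 0.172). With a term for the deeper libraries the direction of the MHC class II list turned (median 0.17, adjusted p = 0.497), and its median against Vehicle was -0.77 in PairFed and -0.78 in GDF15. Only Vehicle 4 and PairFed 1 separate that term from the groups. Vehicle 4 had the highest MHC class II score in Vehicle (0.58) and PairFed 1 the lowest in PairFed (-0.73). The turn rests on these libraries and does not show that PairFed equalled GDF15. Chemokines and cytokines had a median of -0.20 (0 of 17; adjusted p = 0.00618, and adjusted p = 0.420 with an estimated correlation). Within them Cxcl10 was at -0.54 ± 0.18 (adjusted p = 0.187), Ccl2 at -0.60 ± 0.35 (adjusted p = 0.482) and Il1b at -0.80 ± 0.35 (adjusted p = 0.319). Interferon-induced genes had a median of -0.13 (0 of 31; adjusted p = 0.843 with an estimated correlation), with Ifit3b at -0.52 ± 0.16 (adjusted p = 0.154). Recruited monocyte markers were not past the threshold (median -0.01, adjusted p = 0.836), nor were those of NF-kB targets (adjusted p = 0.670), lipid-associated macrophages (adjusted p = 0.247) or fibrosis (median -0.16, adjusted p = 0.0731). With the depth term the fibrosis list was past it at the preset correlation (median -0.35, adjusted p = 2.52e-05, and adjusted p = 0.770 with an estimated correlation), while the chemokine and interferon lists were not (adjusted p = 0.101 and 0.0534). Endothelial markers had a median of -0.27, and of -0.76 with the depth term, with 0 of 22 past the threshold (adjusted p = 0.936 with an estimated correlation), and the immediate-early list a median of 0.32 (0 of 20; adjusted p = 0.730 with an estimated correlation). The immediate-early score differed by 0.29 (exact permutation p = 0.349).

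At the same threshold DESeq2 called 259 genes and limma-voom 73, and 17 of the 96 genes differed at least 2-fold. In 83 of the 96 the groups did not overlap, as in 351 of all genes, or 2.86% against 0.794% by chance. The 5 GDF15 libraries were shallower and 4 of the 5 PairFed libraries deeper, so that within the shallower set PairFed had 1 library. With a term for the deeper libraries 9 genes differed, 7 of them shared with the 96, among them Fkbp5 (1.49 ± 0.23, adjusted p = 0.0415), Slc22a7 and Gin1. In that fit Tsc22d3 was at 1.24 ± 0.21 (adjusted p = 0.0521), and the median of the 6 glucocorticoid-induced genes was 1.15 with a median SE of 0.24, against 1.35 and 0.16 without the term. With the immediate-early score as a covariate 60 genes differed. The count was 52 without Vehicle 5, 30 without GDF15 1, 32 without GDF15 2, 171 without PairFed 1, 57 without PairFed 2, 47 without PairFed 3, 21 without PairFed 4 and 26 without PairFed 5. Of the 21 named genes that differed, 10 stayed past the threshold without each library in turn: Cps1, Cyp27a1, Fkbp5, Gin1, Gpc1, H1f2, Plin5, Sds, Slc22a7 and Tsc22d3. Gin1 was named after its values were seen.

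The responses to GDF15 and to pair feeding were set side by side to see how much of the first the second shared. 13 genes changed in the same direction against Vehicle in both, 11 higher and 2 lower, where 0.364 and 0.150 would be shared if the contrasts were independent. Among them were Fads1, Fads2 and Txnrd3, which rose, and Dynll1, which fell, while Slc22a7 was past the threshold in both with opposite signs. Because both contrasts used the same Vehicle libraries, unchanged groups, a simulated Vehicle group included, were drawn from a common mean per gene. The 2 contrasts with the simulated Vehicle shared a median of 0 genes over 40 simulations. The real Vehicle libraries were not part of these simulations. With the Vehicle libraries split so that each contrast had its own, the median over 20 splits was 0 genes and the highest 12. These 2 values say little about shared controls, because edgeR's test called a median of 0 genes in PairFed vs Vehicle with split Vehicle libraries and in both contrasts of the simulated groups. Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.622, against 0.498 in the simulated unchanged groups and 0.311 (0.211 to 0.403) with split Vehicle libraries. Their covariance was 0.0520 against a simulated 0.0193, a difference of 0.0327. The simulated genes were drawn independently of each other, so the simulations do not show how far r and the covariance vary when genes move together. No conclusion about a shared response is drawn from the differences from the simulated values. The overlap was 0 without Vehicle 1, Vehicle 3, PairFed 2 or PairFed 4, where edgeR's test called no gene in PairFed vs Vehicle, 5 without GDF15 2 or PairFed 5, 6 without GDF15 4, 7 without Vehicle 2 and 8 without GDF15 5. It was 28 without PairFed 1 and 32 without Vehicle 5 or GDF15 3. Of the 96 genes that differed between GDF15 and PairFed, 59 had also changed in the same direction with GDF15 against Vehicle, and 8 had changed in PairFed against Vehicle. The first pair of contrasts shares the GDF15 libraries, which alone favours the same direction, and the number expected from this was not computed. The second pair shares the PairFed libraries with opposite sign, and of the 8 genes only Mknk2 had the same sign in both.

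**Figure D3:**
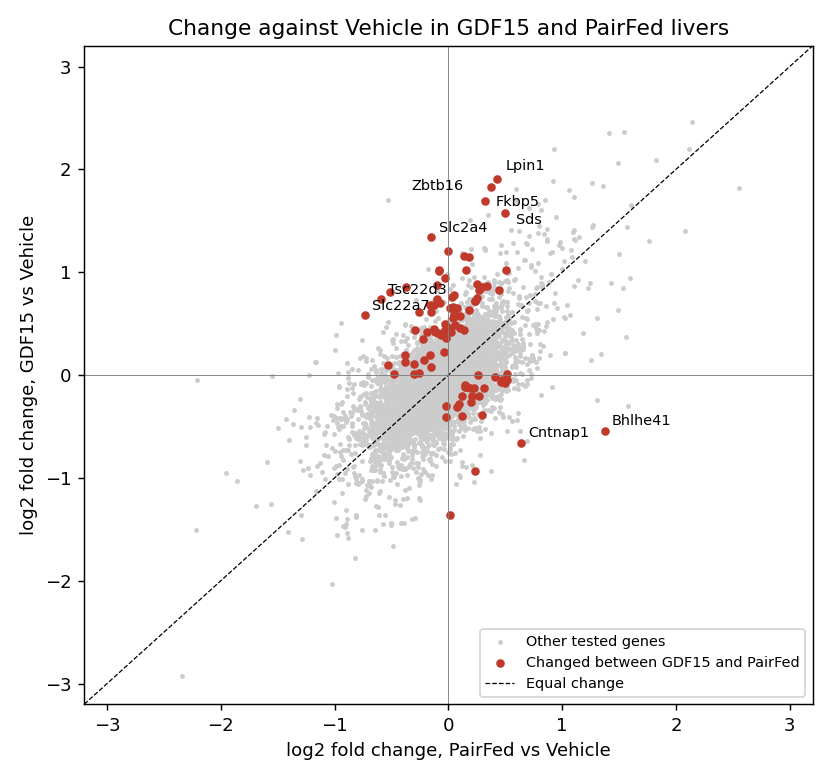
Log2 fold change of each tested gene in PairFed vs Vehicle (x axis) and in GDF15 vs Vehicle (y axis); 4 of the 12274 genes lie outside the axes. Red points are the 96 genes that differed between GDF15 and PairFed, of which 69 lie above the dashed line of equal change, Fkbp5, Zbtb16, Lpin1 and Tsc22d3 among them.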

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

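The tests of a hepatocyte share, of 1 library and of dendritic cells for the fall in antigen presentation, of the deeper libraries, and of the immediate-early covariate in GDF15 vs Vehicle were chosen only after the result was seen.

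Genes of MHC class II and chemokines were lower in GDF15 than in Vehicle. With the immediate-early covariate the MHC class II median was -0.62 (9 of 9 members below 0) against -0.84 without it. H2-DMa, H2-DMb1, Cxcl10 and Ccl5 lost their calls (adjusted p = 0.195, 0.258, 0.146 and 0.706). Lost calls alone do not speak for stress at collection, which stays open because the immediate-early score itself differed between the groups. A larger hepatocyte share of the RNA would lower the markers of every other cell type alike. The MHC class II score moved by -0.873 relative to the Kupffer cell score (exact permutation p = 0.00794), and the chemokine score by -0.60 (exact permutation p = 0.00794). Relative to the endothelial score, that of MHC class II moved by -0.80 (exact permutation p = 0.0397). Against the Vehicle mean, GDF15 scores were 0.06 for Kupffer and -0.02 for endothelial cells. They were -0.49 for recruited monocytes, -0.37 for fibrosis and 0.29 for hepatocytes. The Kupffer and endothelial values argue against hepatocyte share as the whole cause, but a part in the fall stays open. GDF15 1, whose scores stood apart, was not the whole cause: without it the median of the MHC class II list was -0.779 against -0.84, and 3 of 5 members stayed past the threshold. The MHC class II score also moved by -0.464 relative to the dendritic cell score (exact permutation p = 0.0159). That does not settle whether fewer dendritic cells alone would do, because the score need not follow cell number. It holds 7 of the 13 listed markers, some near the floor of detection, such as Batf3 at 1.57 CPM in Vehicle and 0.940 in GDF15. A change in other antigen-presenting cells, such as B cells or recruited monocytes, and lower expression per cell stay open. The difference from PairFed was not past the threshold for any MHC class II gene. The list median of that difference turned from -0.27 to 0.17 with the depth term, which rests on Vehicle 4 and PairFed 1.

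Of the 30 glucocorticoid-induced genes, 6 were higher in GDF15 than in PairFed and 13 higher than in Vehicle (list adjusted p = 0.420 and 0.0462 with an estimated correlation). Against PairFed the median of the 6 called members was 1.35, and it was 1.24 with the immediate-early score as a covariate (5 past the threshold) and 1.39 with clock phase (6 past it), which argues against handling and clock phase as the whole cause as far as these scores follow them. With a term for the deeper libraries the median was 1.15 with 6 of 6 above 0, Fkbp5 stayed past the threshold (1.49 ± 0.23, adjusted p = 0.0415) and the other 5 lost their calls as the median SE went from 0.16 to 0.24, which speaks against depth set as the whole cause of the folds; it is left open because the term rests on Vehicle 4 and PairFed 1, and if these were exchanged every PairFed library and no other would be deeper. Against Vehicle, the median of the 13 called members went from 1.57 to 0.826 with the immediate-early covariate, and Fkbp5 (1.69 ± 0.16 to 1.37 ± 0.17) and Sds (1.57 ± 0.17 to 1.18 ± 0.18) stayed past the threshold. Zbtb16 (1.83 ± 0.25 to 1.57 ± 0.29, adjusted p = 0.117) and Lpin1 (1.90 ± 0.27 to 1.49 ± 0.32, adjusted p = 0.170) kept most of their fold and lost the call with a larger SE, which does not speak for stress at collection as their whole cause, while Per1 (1.32 ± 0.24 to 0.72 ± 0.22) and Tsc22d3 (0.74 ± 0.15 to 0.44 ± 0.16) were closer to 0. Because the score itself differed between the groups, stress at collection and a lasting rise in glucocorticoid cannot be told apart for the list as a whole. Reduced food intake is also part of this contrast and stays open. In PairFed against Vehicle the list median was 0.42, with 27 of 30 members positive. The RNA data hold no hormone level.

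Other splits of the libraries were counted over 100 splits per contrast. In GDF15 vs Vehicle only the real one, 1 of the 100 splits, gave 356 genes (highest other 9). In GDF15 vs PairFed only the real one gave 96 (highest other 37, from exchanging GDF15 5 and PairFed 1). This makes a random division of the libraries unlikely as the source of these counts. It does not speak to a structure that goes with the groups, such as depth set in GDF15 vs PairFed, where 9 genes were called with the depth term. In PairFed vs Vehicle 2 of the 100 gave as many genes as the real 35, and the other, with Vehicle 4 and PairFed 1 exchanged, gave 357, which points to a structure of the samples beside the groups: it parts exactly the 5 shallower from the 5 deeper of these libraries (exact permutation p = 0.00794 for total count), and 380 genes were called with both left out, which leaves every Vehicle library shallower and every PairFed library deeper. On a scale from 0 at the other Vehicle libraries to 1 at the other PairFed libraries, Vehicle 4 lay at 0.580 and PairFed 1 at 0.348 with each other left out, and over the choices of library left out at 0.298 to 0.580 and 0.348 to 0.543, both between the groups, so an exchange of the 2 cannot be told apart from spread among animals. The number of reads alone was argued against, since 282 genes were called after thinning to the smallest total, but a batch or collection day that went with depth stays open and is not given in the sources used here; with clock phase as a covariate 0 genes were called in edgeR's test (507 at an unadjusted p below 0.05; limma-voom 1), where the real split gave 6, but the phase scores part the same libraries (-3.41 to -0.614 against -0.0702 to 1.99), so the covariate takes up that split whatever its cause and clock phase cannot be told apart from it, a reading adopted after the result was seen.

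Of 321 groups of 5 libraries examined for 1 library far from the other 4, 16 had one, and chance gives about 1 in 20, or 16.1. The total count of Vehicle 4 was 12994187 (others 9228127 to 9906526) and that of PairFed 1 was 10133289 (12137462 to 12933324). In CPM, Ciita was at 2.30 in GDF15 1 (3.41 to 3.68 in the others), Clec4f at 56.0 in Vehicle 4 (74.4 to 79.0), Cntnap1 at 16.8 in GDF15 5 (9.75 to 11.8) and Dynll1 at 10.2 in PairFed 4 (11.9 to 12.5). Gdf15 was at 187 in Vehicle 2 (48.0 to 65.3) and at 259 in GDF15 1 (91.7 to 134), H2-M2 at 3.62 in PairFed 3 (1.02 to 1.27) and Pnpla2 at 87.0 in PairFed 1 (108 to 113). Sox9 was at 3.10 in PairFed 2 (6.21 to 7.23) and Zap70 at 6.97 in Vehicle 3 (3.92 to 4.60). Among list scores, T and NK cells were at -0.495 in GDF15 3 (-0.749 to -0.678), B and plasma cells at 1.61 in Vehicle 4 (-0.747 to -0.166), MHC class II at -1.24 in GDF15 1 (-0.736 to -0.641) and interferon-induced genes at 0.385 in Vehicle 2 (-0.173 to -0.0160).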

How the results depend on the processing

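The depth term, the fit of the shallower libraries, the thinned counts and the clock phase and immediate-early covariates were chosen only after the results were seen. Under DESeq2 size factors, upper-quartile factors, no filter, the strict filter and limma-voom, the counts of changed genes stayed within 1.5 times 356, 35 and 96, and scaling moved the median of all genes by less than 0.04 log2. For GDF15 vs Vehicle, PairFed vs Vehicle and GDF15 vs PairFed, the count was 60, 2 and 17 at a change of at least 1 log2 unit, 642, 339 and 259 with DESeq2, and 9, 0 and 60 with the immediate-early covariate. In GDF15 vs Vehicle it was 195 in the fit of 2 groups, 157 with a surrogate variable and 156 in the shallower libraries, where fewer libraries were fitted. In PairFed vs Vehicle it was 74 with a surrogate variable, 6 with the clock phase covariate and 0 with the depth term, and in GDF15 vs PairFed 9 with the depth term. Leaving out 1 library gave 134 (GDF15 2) to 476 (GDF15 3), 0 (Vehicle 1, Vehicle 3, PairFed 2 or PairFed 4) to 135 (PairFed 1) and 21 (PairFed 4) to 171 (PairFed 1) genes. Beside these counts of 0 from edgeR's test, 1361 (depth term), 1347 (immediate-early covariate), 1766, 1517, 1710 and 1780 genes had an unadjusted p below 0.05, limma-voom called 0 and DESeq2 62 to 183. The lists past the threshold were 3, 0 and 0 with an estimated correlation, 0, 0 and 0 with it and the depth term, and 13, 0 and 0 with fry, against 23, 20 and 12; without 1 library they were 21 to 24, 16 to 22 and 9 to 15. The overlap of 13 genes was 0 (Vehicle 1) to 32 (Vehicle 5) without 1 library. With split Vehicle libraries its median was 0, which was fixed by a median of 0 genes called by edgeR's test in PairFed vs Vehicle there and says nothing about shared controls. The correlation of 0.622 became 0.509 with no filter, 0.311 with split Vehicle libraries and 0.556 to 0.662 without 1 library. The direction turned for Nr3c1 in GDF15 vs Vehicle without GDF15 5 (adjusted p = 0.986; 0.541 to 0.986 without 1 library), with the clock phase covariate (0.911) and with the immediate-early covariate (0.998), as for Gdf15 with the latter (0.998) and Per1 in GDF15 vs PairFed with it (0.962). It also turned for Ccl2 in PairFed vs Vehicle with the depth term (adjusted p = 0.923) and the clock phase covariate (0.920), for the fibrosis list in GDF15 vs Vehicle with a surrogate variable (adjusted p = 0.0610), and for the MHC class II and lipogenesis lists in GDF15 vs PairFed with the depth term (adjusted p = 0.497 and 0.719; 0.927 for both with an estimated correlation). In GDF15 vs PairFed the depth term, with the preset correlation, took 4 more lists past the threshold: cholesterol, which turned from a median of 0.06 to -0.20 (adjusted p = 0.00440), B and plasma cells, which turned from -0.21 to 0.81 (adjusted p = 0.000134), fibrosis (adjusted p = 2.52e-05) and antioxidant genes (adjusted p = 0.00134). It ended the call of 7: MHC class II, lipogenesis, chemokines, interferon-induced, endoplasmic reticulum stress, immediate-early and receptor and steroid genes. In PairFed vs Vehicle it added B and plasma cells (adjusted p = 5.32e-07), acute phase (0.00317) and lipogenesis (0.000935), and in GDF15 vs Vehicle endoplasmic reticulum stress (0.0104). The depth term rests on Vehicle 4 and PairFed 1. Vehicle 4 had a B and plasma cell score of 1.61, against -0.747 to -0.166 in the other Vehicle libraries. The B and plasma cell calls with the depth term can therefore come from 1 library. Where the number of libraries or genes does not account for a change, the cause was not tested. Of the named genes past the threshold, 4 of 43 (Cps1, Fkbp5, Gin1 and Sds), 0 of 14 and 3 of 21 (Fkbp5, Gin1 and Slc22a7) stayed past it under all the alternatives run for single genes, covariates included. Depth limits genes of few counts, such as Tnf.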

Other observations

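The matching of neighbour draws for expression, the count without overlapping or similarly named pairs, and the choice of Gin1 and of the opposite signs of Slc22a7 came only after the results were seen.

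In GDF15 vs Vehicle, 24 pairs of neighbouring genes changed in the same direction, against a median of 6 and at most 17 in 10000 random draws of as many tested genes, the test planned, and at most 18 in draws also matched for expression. Without pairs that overlap or share a name stem there were 19, against at most 16 in matched draws. Neighbours were next tested genes on a chromosome, up to 1784139 bp apart (Sall1 and Chd9). A candidate explanation is shared regulation of neighbouring genes. Reads counted for a neighbour could add to pairs that overlap, since the strand setting is not given in the sources used here. The 19 pairs do not overlap by their RefSeq positions, and their number argues against such reads as the whole cause. In GDF15 vs PairFed there were 2 such pairs, no more than the 95th percentile of the draws, which was 2.

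Added lists were tested as 9 list tests adjusted together. In GDF15 vs Vehicle, MHC class I genes had a median of -0.173 (adjusted p = 0.00573, and adjusted p = 0.374 with an estimated correlation), autophagy genes of 0.0538 (adjusted p = 0.0139, and adjusted p = 0.374 with an estimated correlation) and heat shock genes of -0.0540 (adjusted p = 0.0607). In PairFed vs Vehicle, heat shock genes had a median of -0.187 (adjusted p = 4.36e-05, and adjusted p = 0.299 with an estimated correlation) and autophagy genes of 0.0962 (adjusted p = 0.00448, and adjusted p = 0.299 with an estimated correlation), while MHC class I was not past the threshold (adjusted p = 0.310). In GDF15 vs PairFed, MHC class I genes had a median of -0.0899 (adjusted p = 0.0607), heat shock genes of 0.104 (adjusted p = 0.00573, and adjusted p = 0.374 with an estimated correlation), and autophagy genes were not past the threshold (adjusted p = 0.585). The lists that lost their call with an estimated correlation stay undecided.

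Gin1, a gene of little known function in the liver, was at 15.7 ± 0.782 CPM in GDF15, 8.59 ± 0.623 in Vehicle and 8.01 ± 0.628 in PairFed (mean ± SD, n = 5 each). It rose by 0.87 ± 0.09 against Vehicle (adjusted p = 6.33e-05) and was higher by 0.97 ± 0.09 than in PairFed (adjusted p = 2.13e-05). It overlaps a neighbouring gene, whose reads it can share. Slc22a7 was at 27.3 ± 3.40 CPM in GDF15, 18.2 ± 3.46 in Vehicle and 10.9 ± 1.70 in PairFed.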
